A study of Arabidopsis thaliana with 22 samples.

How the data were processed

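Per the labels' protocols, RNA of mature Arabidopsis thaliana leaves was sequenced from the wild type and from the T-DNA insertion mutants hpr1, shm1, glyk1 and pglp1, each grown in air with 1% CO2 (HC). Part of the plants was moved to 0.038% CO2 (LC) at the end of a dark period and sampled 8 h after the light came on. Groups were taken from the sample titles: 3 libraries of the wild type and 2 of each mutant at each CO2 level, 22 libraries in 10 groups. The design text calls the replicates biological, and nothing else describes whether plants, pools or growth batches were independent, so the p-values measure the spread between these libraries. Per the labels' protocols, polyadenylated RNA was sequenced either as single reads or as read pairs, on HiSeq machines of different models, and which library had which mode is not given.

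Per the submitters' processing notes, base calls were made with CASAVA, reads were assigned to TAIR9 or TAIR10 genes, and edgeR was used for testing; the aligner is not given in the sources used here. Per the file headers, the deposited table holds a read count and an RPKM value per locus and library. It also holds the authors' p-value and q-value with a log2 fold change per comparison, as deposited. Counts were the only input of the tests here, the RPKM column served to check rows, and the authors' deposited q-value served only for counts of loci in the additional observations.

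The table has 25680 loci, of which 25479 have an entry in the TAIR10.1 annotation used for names and 10184 have a symbol. Coordinates refer to TAIR10.1, whose chromosome sequences carry the coordinates of TAIR10, and were used only to place the targeted genes. Summed counts per library ran from 5.91 M (1e6) (hpr1 LC replicate 1) to 194 M (shm1 LC replicate 1). Values are given as CPM (counts per 1e6 counts), and the shallower the library the fewer counts stand behind a CPM value.

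In wild-type LC replicate 3, 4920 rows (19.2% of the table) carry counts that belong to nearby rows. They form 3 blocks: 21 rows from AT1G24620 to AT1G25098, 120 rows from AT2G40960 to AT2G42040 and 4779 rows from AT3G06660 to AT3G66658. Windows of 21 loci were correlated with the mean of reference libraries at shifts of up to 10 rows. The reference was the other wild-type libraries for a wild-type library. For a mutant library it was the other libraries of its genotype or its CO2 level, wild-type LC replicate 3 included in LC. A window was taken as displaced where a shift raised r by at least 0.3 to at least 0.8. Displaced windows were joined over gaps of up to 150 rows, and the other 21 libraries have none. The deposited RPKM values of this library follow the length of the row they stand on (median ratio 1.000 over 1863 rows). These cells were treated as missing. This was decided after the defect was seen and before any test was run; the fit with all rows as deposited, which is the one fixed before the data were examined, is given beside the main counts.

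Tests used edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr, a design of 10 group means and robust quasi-likelihood F tests; all 22 libraries were fitted together. 16754 loci were tested in 22 libraries and 3618 loci with displaced rows in 21, and p-values were adjusted over the merged 20372 loci (Benjamini and Hochberg, threshold 0.05). There were 17 comparisons: LC against HC in each genotype, each mutant against the wild type at each CO2 level, and for each mutant its response to LC minus that of the wild type. All mutants at one CO2 level share the same wild-type libraries, so their comparisons are not independent. Adjusted p-values of genes are from edgeR's quasi-likelihood test unless another tool is named. SE is that of the log2 fold change, from the F statistic. CPM are TMM-normalised, and ± gives the SD over libraries. Where a group had 0 counts a fold is given as a bound from 3 counts in that group; where it had 1 to 3 counts a ratio of summed counts is given with its 95% counting interval. Such bounds and intervals cover counting error only. Fitted values of these genes depend on the prior count.

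Gene lists (27 lists, 386 loci) were written from textbook knowledge before the data were examined: photorespiration, Calvin-Benson cycle, light harvesting, photosystem subunits, chlorophyll synthesis, carbonic anhydrases, starch and sucrose, carbon starvation, stomatal movement, abscisic acid (ABA) response, oxidative stress, mitochondrial dysfunction, senescence, anthocyanins and flavonoids, salicylic acid defence, jasmonate, nitrogen assimilation, the phosphorylated serine pathway, circadian clock, heat shock, endoplasmic reticulum (ER) stress, reference genes, and markers of guard cells, epidermis, phloem, floral organs and roots. Lists were tested with limma 3.58.1 (cameraPR on signed z values, preset inter-gene correlation 0.01), adjusted over the lists of a comparison. Members that pass a threshold adjusted over the list alone are counted separately, in those words. The same test with the correlation estimated from the data is named where it ends a call.

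Genes named in the report follow a rule: the targeted genes in every group; per main comparison the 6 largest rises and 6 largest falls among genes with a symbol, an adjusted p below the threshold, at least 5 mean CPM and every library of one group above every library of the other; up to 3 genes per list that passed or had at least 3 changed members, by adjusted p. In the other comparisons the numbers were 3, 3 and 1, and for changes common to all 4 mutants 6 and 6 by the largest of the 4 p-values. Not all of them are printed.

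The tools were tested on simulated counts with 200 changed genes. Of 100 genes changed 4-fold edgeR found 90, 78 and 79 in the 3 simulated comparisons, and of 100 changed 2-fold 36, 18 and 15; false calls were 4 of 130, 10 of 106 (9.4%, over the threshold of 5%) and 4 of 98. DESeq2 1.42.0 made 29 false calls of 179, 37 of 152 and 25 of 153, and 9 and 6 in comparisons without any change, more than its threshold allows. Of 100 random lists of unchanged simulated genes, 2 had an unadjusted p under 0.05 in the list test. Simulated genes were drawn independently, so this does not test the preset correlation for lists of correlated genes.

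Wild-type HC and LC replicate 3 differ from all other libraries in how counts relate to RPKM: their ratio, scaled by library size, was at the lowest of all libraries, ties included, for all of 3297 loci, while each other library reached that lowest value for 15.0% to 52.1% of them. This processing batch holds no mutant. Whether equal replicate numbers mark paired samples was checked by the correlation of residuals: it was 0.47, 0.17 and 0.43 for the 3 wild-type pairs, and between −0.33 and 0.05 in the mutants. Alternatives fixed before the data were examined were DESeq2 size factors, DESeq2's test, no filter, a filter of 5 CPM in 2 libraries, only the groups compared, a replicate block and leaving out each library, and for lists an estimated correlation and fry. Alternatives added after the data were seen were all rows as deposited, displaced rows dropped, both wild-type replicate 3 libraries left out, a block in the 6 wild-type libraries alone and crossed hpr1 numbers. For fry and for the estimated correlation, wild-type LC replicate 3 was left out, so fry rests on 21 libraries. A call lost with fry can therefore come from that library as well as from the change of test. Nothing else was left out.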

Results

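Leaves of the wild type and of 4 Arabidopsis mutants of photorespiration, the pathway that salvages carbon from phosphoglycolate after Rubisco has bound oxygen, were compared in air with 1% CO2 (HC) and after a shift to 0.038% CO2 (LC). The mutants carry T-DNA insertions in the genes of peroxisomal hydroxypyruvate reductase (hpr1), mitochondrial serine hydroxymethyltransferase (shm1), glycerate kinase (glyk1) and phosphoglycolate phosphatase (pglp1). The series concerns how photorespiration, photosynthetic metabolism and stomata respond to CO2. Summed counts, in 1e6 reads (M), were 82.0, 66.5 and 18.1 M in wild-type HC and 24.6, 11.98 and 17.2 M in wild-type LC. They were 32.5 and 27.3 M in hpr1 HC, 5.91 and 91.9 M in hpr1 LC, 33.7 and 28.0 M in shm1 HC, and 194 and 65.3 M in shm1 LC. In glyk1 HC they were 91.2 and 78.6 M, in glyk1 LC 75.0 and 57.7 M, in pglp1 HC 9.14 and 17.9 M, and in pglp1 LC 12.4 and 16.1 M.

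Each targeted transcript was lower in both libraries of its own mutant than in every wild-type library, at both CO2 levels. HPR1 (AT1G68010) stood at 1.41 ± 0.116 CPM in hpr1 HC (SD, n = 2) against 324 ± 110 CPM in the wild type (n = 3), a log2 fold change of −7.84 (SE 0.47, adjusted p = 5.07e-07). In LC it stood at 3.63 ± 1.82 against 458 ± 77.4 CPM (−7.06, SE 0.46, adjusted p = 1.51e-06, adjusted p = 0.225 when only these 2 groups were fitted). SHM1 (AT4G37930) kept 97.2 ± 16.5 CPM in shm1 HC against 1881 ± 419 CPM (−4.27, SE 0.44, adjusted p = 0.000905, adjusted p = 0.0675 when only these 2 groups were fitted). That call was also lost without shm1 HC replicate 1 (adjusted p = 0.0832) or replicate 2 (adjusted p = 0.104). In LC SHM1 stood at 40.3 ± 20.7 against 1631 ± 645 CPM (−5.34, SE 0.46, adjusted p = 2.33e-07). GLYK (AT1G80380) fell to 1.41 ± 0.0753 against 181 ± 34.8 CPM in glyk1 HC (−7.01, SE 0.40, adjusted p = 1.97e-07) and to 0.766 ± 0.198 against 133 ± 50.9 CPM in LC (−7.44, SE 0.41, adjusted p = 7.41e-09).

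Phosphoglycolate phosphatase is read from PGLP1 (AT5G36700) and from an identical copy, AT5G36790; their coding sequences are 100% identical and share 990 of 990 windows of 100 bp, so how the counts divide between them is uncertain. AT5G36790 stood at 11.7 ± 0.549 CPM in pglp1 HC against 270 ± 84.9 CPM in the wild type (−4.53, SE 0.34, adjusted p = 1.02e-05). In LC it stood at 7.09 ± 0.561 against 250 ± 67.1 CPM (−5.14, SE 0.35, adjusted p = 2.03e-08). PGLP1 stood at 10.9 ± 1.07 against 89.4 ± 5.04 CPM in HC (−3.03, SE 0.58, adjusted p = 0.0122) and at 5.11 ± 0.573 against 71.3 ± 62.6 CPM in LC (−3.80, SE 0.61, adjusted p = 7.33e-05). The HC call of PGLP1 was lost without pglp1 HC replicate 1 (adjusted p = 0.148) or replicate 2 (adjusted p = 0.211). In TAIR10.1, HPR1 lies on chromosome 1 from 25493193 to 25496053 (plus strand, 13 exons) and GLYK on chromosome 1 from 30217116 to 30220595 (plus strand, 11 exons). SHM1 lies on chromosome 4 from 17831731 to 17835017 (minus strand, 15 exons), PGLP1 on chromosome 5 from 14421182 to 14424610 and AT5G36790 on chromosome 5 from 14480482 to 14483927 (both minus strand, 12 exons). Counts are per gene and do not show on which side of an insertion the remaining reads lie.

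**Figure D1:**
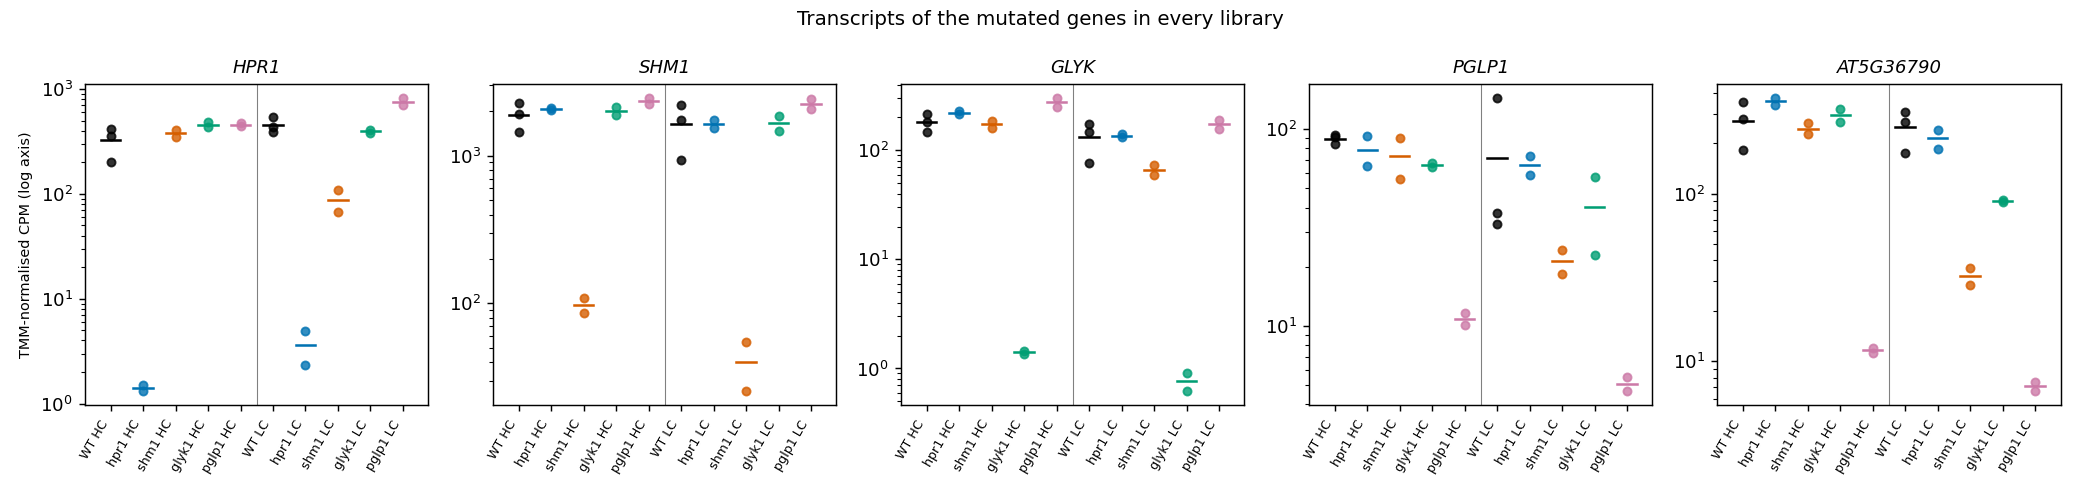
Targeted transcripts per library (TMM-normalised CPM, log axis; points are libraries, short lines group means, HC left and LC right of the vertical line). In its own mutant each is lower than in all wild-type libraries, with log2 fold changes from −3.03 (PGLP1 in HC) to −7.84 (HPR1 in HC).

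In the wild type, 4 of 20372 tested genes changed between HC and LC, 1 up and 3 down, with all rows as deposited as well; 1907 had an unadjusted p under 0.05. TCH4 (AT5G57560), a xyloglucan-modifying enzyme of the cell wall, rose from 1.92 ± 0.584 to 17.5 ± 10.5 CPM (SD, n = 3 each; log2 fold change 3.21, SE 0.42, adjusted p = 0.00638). LBD41 (AT3G02550), a transcription factor known to rise at low oxygen, fell from 24.6 ± 1.28 to 2.16 ± 0.776 CPM (−3.54, SE 0.29, adjusted p = 1.9e-05). AT5G15120, a plant cysteine oxidase, fell by 5.11 log2 units (SE 0.37, adjusted p = 6.19e-06) and AT3G06435 by 3.34 (SE 0.36, adjusted p = 0.000545). This pair lies outside the rule for named genes and was picked after its values were seen. None of the targeted genes changed (log2 fold changes from −0.45 for GLYK to 0.50 for HPR1, adjusted p from 0.625 to 0.941).

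As a group, the 22 ABA response genes shifted up by a median of 1.28 log2 units (list test adjusted p = 1.17e-21, 0.0326 with an estimated correlation and 0.0912, not passed, with fry). Their median was 0.69 without LC replicate 1 and 1.69 without LC replicate 2. Of them 0 passed over all genes and 16 adjusted over the list alone. RAB18 (AT5G66400), a dehydrin, stood at 176 ± 196 against 16.7 ± 2.70 CPM (3.40, SE 0.68, adjusted p = 0.128), HAI2 (AT1G07430) at 2.93 (SE 0.71) and ABI2 (AT5G57050) at 1.15 (SE 0.28, adjusted p = 0.2 for both protein phosphatase genes). The 16 anthocyanin and flavonoid genes shifted up by a median of 3.86 (adjusted p = 1.87e-17, 0.0326 with an estimated correlation and 0.0912 with fry), with 11 past the threshold adjusted over the list alone. LDOX (AT4G22880) stood at 298, 9.92 and 3.61 CPM in the 3 LC libraries against 0.326 ± 0.198 CPM in HC (8.31, SE 1.68, adjusted p = 0.128). UGT75C1 (AT4G14090) stood at 5.35 (SE 1.11) and TT19 (AT5G17220) at 6.31 (SE 1.32, adjusted p = 0.133 for both). Without LC replicate 1, the library with most of the LDOX transcript, the median of this list was 1.19. Higher lists whose call was lost with an estimated correlation were carbon starvation (median 0.36, adjusted p = 0.0243, adjusted p = 0.766 with an estimated correlation), senescence (0.55, 0.00701; 0.485) and circadian clock (0.26, 0.00287; 0.383). The senescence median was 0.14 without LC replicate 1 and 0.86 without LC replicate 2, and those of carbon starvation and clock were 0.20 and 0.17 without both replicate 3 libraries. In the first, ASN1 (AT3G47340), an asparagine synthetase, stood at 2.04 (SE 0.70, adjusted p = 0.37) while DIN11 (AT3G49620) had 2 counts in LC against 793 in HC (98.0-fold, 27.0 to 811) without passing (adjusted p = 0.377, 0.0145 with DESeq2). The phosphorylated serine pathway shifted down (median −0.70, −0.20 without both replicate 3 libraries, adjusted p = 0.00887, adjusted p = 0.177 with an estimated correlation). In it PSAT1 (AT4G35630), phosphoserine aminotransferase, stood at 33.7 ± 13.3 against 78.9 ± 13.7 CPM (−1.22, SE 0.34, adjusted p = 0.254) and PGDH1 (AT4G34200) at −1.14 (SE 0.40, adjusted p = 0.373).

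No member of the photorespiration, Calvin-Benson, light harvesting, photosystem or chlorophyll synthesis lists changed in the wild type (medians −0.08, −0.18, −0.26, −0.20 and −0.38; list test adjusted p = 0.397, 0.245, 0.397, 0.223 and 0.078). All these medians turned positive without LC replicate 1 (0.08, 0.09, 0.20, 0.17 and 0.06). For photorespiration the test direction was up and the mean 0.07. The epidermis markers, a list of 6, shifted down by 0.40 without passing (adjusted p = 0.057, adjusted p = 0.0347 with a replicate block). The remaining lists did not pass: carbonic anhydrases (median 0.17, adjusted p = 0.176), starch and sucrose (0.22, 0.078), stomatal movement (−0.06, 0.977), oxidative stress (−0.16, 0.994), mitochondrial dysfunction (0.17, 0.223), salicylic acid (0.18, 0.35), jasmonate (−0.08, 0.397), and nitrogen assimilation (−0.11, 0.655). Nor did heat shock (0.25, 0.333), ER stress (0.00, 0.994), guard cell (−0.24, 0.402), phloem (0.27, 0.176), root (0.01, 0.958) and reference genes (−0.05, 0.69) pass, or the single tested floral gene (−0.86, 0.489). Mean and median differed in sign for jasmonate (mean 0.34), nitrogen assimilation (0.04) and ER stress (−0.08). The medians of stomatal movement and reference genes turned to 0.02 with DESeq2 size factors, and those of starch, salicylic acid, heat shock and guard cell genes changed sign without LC replicate 1. There ER stress stood at −1.31, jasmonate at −0.81 (0.16 without LC replicate 2), oxidative stress at −0.43 and nitrogen assimilation at −0.36.

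The wild-type count depended on single libraries: without LC replicate 2 it was 183 genes (114 up, 69 down). Among them were RAB18 (3.91, adjusted p = 0.00359), ABI2 (1.39, adjusted p = 0.0269) and HAI2 (3.33, adjusted p = 0.041) of the ABA list, and LDOX (8.84, adjusted p = 0.0249), UGT75C1 (5.89, adjusted p = 0.0164) and TT19 (6.83, adjusted p = 0.0265). Without HC replicate 1 it was 9, without HC replicate 2 TCH4 lost its call (adjusted p = 0.11), DESeq2 called 212, and edgeR on the 6 wild-type libraries alone called 0 (619 with an unadjusted p under 0.05). Rank correlations with the wild-type HC libraries were 0.966 to 0.978 for LC replicate 2, 0.899 to 0.959 for replicate 1 and 0.920 to 0.932 for replicate 3.

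**Figure D2:**
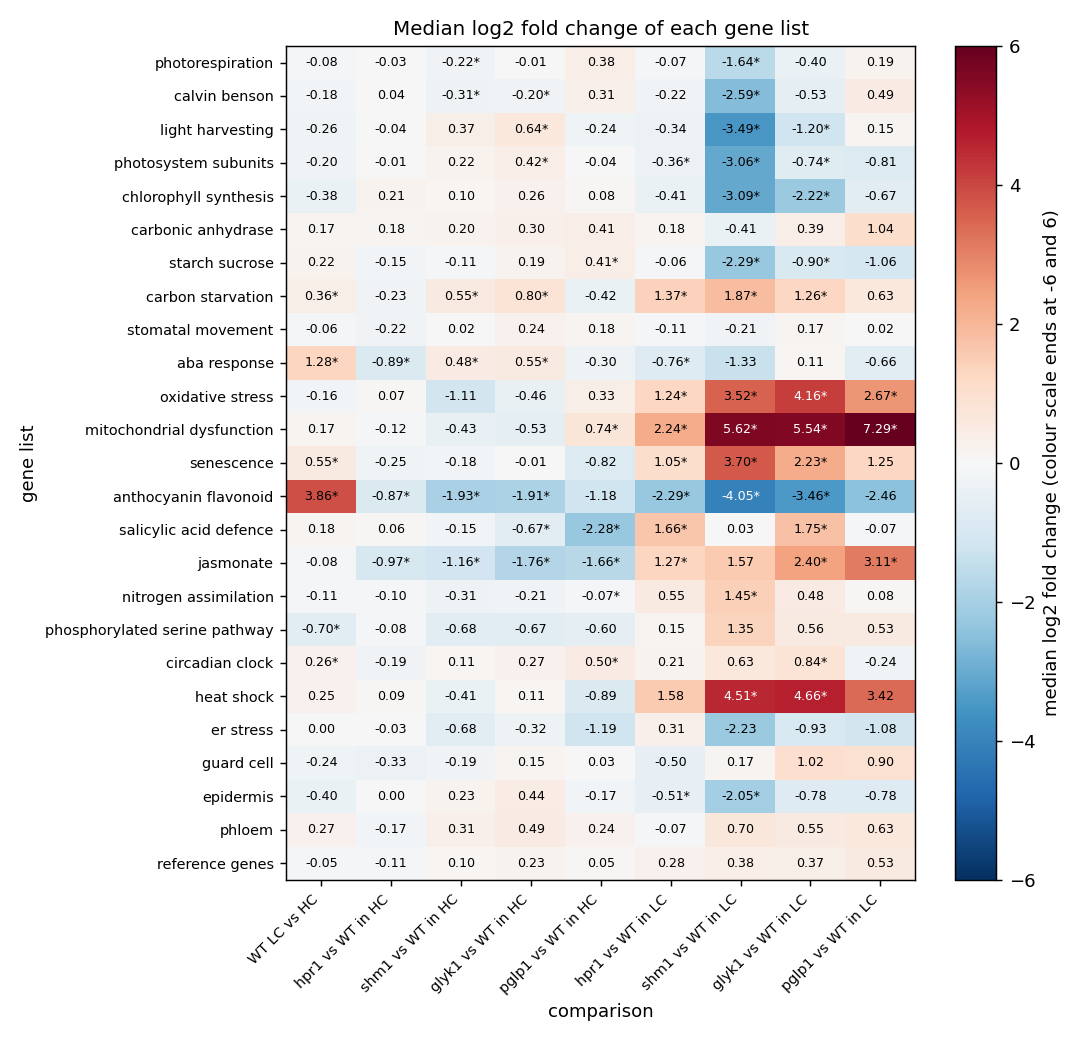
Median log2 fold change of 25 gene lists in LC against HC in the wild type and in each mutant against the wild type (colour scale ends at ±6; stars mark list tests with an adjusted p under 0.05 at the preset correlation). The mitochondrial dysfunction list had medians of 2.24, 5.62, 5.54 and 7.29 in the 4 mutants in LC.

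In hpr1 in LC, 578 genes differed from the wild type, 433 up and 145 down (275 and 84 with all rows as deposited, 239 and 77 with a replicate block). In the main fit 3735 had an unadjusted p under 0.05. CYP81D11 (AT3G28740), a cytochrome P450, rose from 0.171 ± 0.150 CPM (n = 2) to 157 ± 17.2 CPM (n = 2; log2 fold change 10.09, SE 0.66, adjusted p = 2.39e-06). UGT74E2 (AT1G05680), a glucosyltransferase that responds to hydrogen peroxide, rose from 0.317 ± 0.173 to 110 ± 134 CPM (8.44, SE 1.04, adjusted p = 0.000802). MIPS1 (AT4G39800), an inositol phosphate synthase, fell from 164 ± 10.7 to 28.1 ± 5.48 CPM (−2.54, SE 0.26, adjusted p = 0.000154). UGT73C1 (AT2G36750) rose by 5.12 (SE 0.79, adjusted p = 0.00786) and DIN10 (AT5G20250), a raffinose synthase family gene induced in the dark, from 14.4 ± 11 to 245 ± 183 CPM (4.1, SE 0.66, adjusted p = 0.00567). DTX1 (AT2G04040), an efflux carrier (7.41, SE 1.4, adjusted p = 0.0126), GSTU24 (AT1G17170), a glutathione transferase (5.09, SE 0.95, adjusted p = 0.0116) and ZAT10 (AT1G27730), a zinc finger factor (2.33, SE 0.48, adjusted p = 0.0179), rose as well. So did AOX1A (AT3G22370), the alternative oxidase (153 ± 109 against 40.0 ± 8.09 CPM, 1.93, SE 0.42, adjusted p = 0.0249). Without LC replicate 1 of hpr1 these 4 genes lost their call (adjusted p = 0.182, 0.143, 0.122 and 0.231), AOX1A also without wild-type LC replicate 2 (adjusted p = 0.119). XTH31 (AT3G44990), a cell wall enzyme, fell by 5.04 (SE 0.89, adjusted p = 0.0113, adjusted p = 0.0743 without hpr1 LC replicate 1 and 0.154 with all rows as deposited). JAZ8 (AT1G30135), a jasmonate repressor, rose by 3.49 (SE 0.60, adjusted p = 0.00786, adjusted p = 0.083 without hpr1 LC replicate 2).

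Of the lists in hpr1 LC, oxidative stress held with an estimated correlation but not with fry: 6 of 13 genes higher, median 1.24 (adjusted p = 1.51e-06, 0.0395 with an estimated correlation and 0.0644 with fry). This median was 2.76 without wild-type LC replicate 1 and 0.84 without wild-type LC replicate 2. Mitochondrial dysfunction (4 of 12 higher, 10 adjusted over the list alone, median 2.24, adjusted p = 3.06e-08), carbon starvation (3 of 21, 9 alone, 1.37, 4.32e-08), jasmonate (2 of 17, 5 alone, 1.27, 8.46e-05), salicylic acid (1 of 22, 9 alone, 1.66, 0.000246) and senescence (1 of 9, 1.05, 0.00242) were higher at the preset correlation only. With an estimated correlation they had adjusted p = 0.138, 0.162, 0.398, 0.55 and 0.384. ABA response (1 of 22 lower, 5 alone, median −0.76, adjusted p = 7.4e-05), anthocyanins (0 of 16, −2.29, 5.27e-06), photosystem subunits (0 of 22, −0.36, 0.0113) and epidermis markers (0 of 6, −0.51, 0.0117) were lower at the preset correlation only. With an estimated correlation these had adjusted p = 0.483, 0.384, 0.682 and 0.36. Without wild-type LC replicate 2 the medians of salicylic acid, senescence, ABA response and photosystem subunits were 1.17, 0.63, −1.17 and −0.27. Without wild-type LC replicate 1 they were 2.57, 1.79, −0.27 and −0.73. The anthocyanin median turned to 0.12 there, and the photosystem call was lost with a replicate block (adjusted p = 0.436) while starch and sucrose gained one (from 0.176 to 0.0281). PSBS (AT1G44575), the sensor of photoprotective quenching, stood at 615 ± 79.3 against 1005 ± 272 CPM (−0.71, SE 0.29, adjusted p = 0.203). Photorespiration (1 up and 1 down of 32, the latter HPR1, median −0.07, adjusted p = 0.191), light harvesting (−0.34, 0.0872), chlorophyll synthesis (−0.41, 0.0999) and nitrogen assimilation (0.55, 0.143) did not pass. Without wild-type LC replicate 1 light harvesting and chlorophyll synthesis stood at −0.77 and −0.74, and without replicate 2 at −0.13 and −0.21, with nitrogen assimilation at 0.29. Light harvesting and photosystem subunits stood at −0.07 and −0.09 without both wild-type replicate 3 libraries. When only these 2 groups were fitted 0 genes were called (1574 at an unadjusted p under 0.05; DESeq2 on all libraries called 938 up and 495 down). Without hpr1 LC replicate 1, wild-type LC replicate 2 or wild-type LC replicate 1 the calls were 152 up and 24 down, 224 and 137, and 916 and 453.

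In shm1 in LC, 13496 of 20372 genes differed from the wild type, 6766 up and 6730 down (6114 and 6365 with all rows as deposited, 6736 and 6915 with DESeq2 size factors). Transcripts of photosynthesis were lower. CAB1 (AT1G29930), a light harvesting protein, stood at 1194 ± 952 CPM (n = 2) against 23400 ± 14800 CPM (n = 3; log2 fold change −4.29, SE 0.62, adjusted p = 2.3e-05). CHLG (AT3G51820), chlorophyll synthase, stood at 8.22 ± 5.89 against 140 ± 62.8 CPM (−4.05, SE 0.48, adjusted p = 4.94e-06). FBA1 (AT2G21330), a plastid aldolase, fell by 3.76 (SE 0.39, adjusted p = 9.86e-07). All 18 light harvesting genes (median −3.49, list test adjusted p = 2.59e-05), all 22 photosystem genes (−3.06, 1.47e-06) and 15 of 16 chlorophyll synthesis genes (−3.09, 4.56e-05) were lower. So were 21 of 24 Calvin-Benson genes (2 higher, −2.59, 3.02e-05), 24 of 32 photorespiration genes (5 higher, −1.64, 0.00098) and 20 of 27 starch and sucrose genes (2 higher, −2.29, 2.59e-05). Among them were LHCB5 (AT4G10340, −3.79, SE 0.53), PSBS (−3.07, SE 0.32), PSAL (AT4G12800, −3.10), the transcription factor GLK1 (AT2G20570, −2.14, SE 0.22), FBA2 (AT4G38970, −3.02), DPE1 (AT5G64860), a starch disproportionating enzyme (−3.64, SE 0.31), PGM1 (AT5G51820, −3.64) and SS1 (AT5G24300, −3.12). HPR1 (−2.37, SE 0.35, adjusted p = 2.87e-05) and AT5G36790 (−2.95, SE 0.31, adjusted p = 1.1e-06) were lower too. TKL2 (AT2G45290), a transketolase, rose by 2.24 (SE 0.21, adjusted p = 4.17e-07) and CA3 (AT1G23730), a carbonic anhydrase, by 4.48 (SE 0.69, adjusted p = 4.27e-05). CA1 (AT3G01500) fell by 2.67 (SE 0.77, adjusted p = 0.00609, adjusted p = 0.0681 without shm1 LC replicate 2). The list calls of this paragraph were lost with an estimated correlation (adjusted p = 0.299 to 0.442).

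In shm1 LC, AOX1A went from 40.0 ± 8.09 (n = 2) to 1583 ± 59.2 CPM (5.37, SE 0.48, adjusted p = 5.39e-07). UPOX (AT2G21640), a mitochondrial protein induced by peroxide, rose from 4.07 ± 1.47 to 343 ± 51.3 CPM (6.42, SE 0.54, adjusted p = 1.81e-07) and GSTU25 (AT1G17180) from 0.0516 ± 0.049 to 1327 ± 385 CPM (14.31, SE 1.28, adjusted p = 3.92e-07). WRKY6 (AT1G62300), a senescence regulator, rose from 10.4 ± 3.73 to 660 ± 66.4 CPM (5.98, SE 0.38, adjusted p = 3.07e-08). All 12 mitochondrial dysfunction genes (median 5.62, adjusted p = 2.59e-05), 9 of 13 oxidative stress genes (2 lower, 3.52, 0.0107), and 7 of 9 senescence genes (3.70, 0.00953) were higher. So were 5 of 7 heat shock genes (4.51, 0.0342), 13 of 21 carbon starvation genes (1 lower, 1.87, 0.0244) and 9 of 14 nitrogen assimilation genes (1 lower, 1.45, 0.0244). Anthocyanin genes (14 of 16 lower, 1 higher, −4.05, 0.00953) and epidermis markers (4 of 6, −2.05, 0.0107) were lower. Without wild-type LC replicate 1 the anthocyanin median was −2.58 and that of oxidative stress 5.37. The list calls of this paragraph were lost with an estimated correlation (adjusted p = 0.299 to 0.499). NRT1.1 (AT1G12110), the nitrate transporter, rose from 24.4 ± 3.98 to 861 ± 207 CPM (5.14, SE 0.24, adjusted p = 1.14e-08). GDH2 (AT5G07440), glutamate dehydrogenase, rose by 5.36 (SE 0.37) and PSAT1 from 33.7 ± 13.3 to 1403 ± 317 CPM (5.38, SE 0.42, adjusted p = 1.03e-07). HSP90.1 (AT5G52640, 6.49, SE 0.78), ZAT10 (5.05, SE 0.52), JAZ8 (7.40, SE 0.59), DIN10 (5.35, SE 0.69) and the potassium channel AKT1 (AT2G26650, 4.88, SE 0.43) rose with adjusted p from 1.96e-07 to 8.58e-06. LDOX fell by 9.05 (SE 2.07, adjusted p = 0.00131). UBQ10 (AT4G05320), often used as a reference, rose from 1390 ± 359 to 6272 ± 769 CPM (2.17, SE 0.30, adjusted p = 1.51e-05).

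The largest changes in shm1 LC involved transcripts all but absent from the wild type in LC. DIN11 was 32800-fold higher (9080 to 271000), SUC7 (AT1G66570), a sucrose transporter gene, 17500-fold (3140 to 690000), LCR67 (AT1G75830), a defensin-like gene, at least 1090-fold, NAP12 (AT2G37010) at least 807-fold and RGF7 (AT3G02240) at least 486-fold. Lists without a call were stomatal movement (7 up, 8 down of 22, median −0.21, adjusted p = 0.87, 0.47 without both wild-type replicate 3 libraries, mean 0.19) and ABA response (6 up, 12 down, −1.33, 0.249). Salicylic acid genes had no call either (9 up, 4 down, 0.03, 0.737; median 1.82 without wild-type LC replicate 1 and −0.33 without replicate 2). The same held for jasmonate (8 up, 2 down, 1.57, 0.159), phosphorylated serine pathway (3 up, 2 down of 6, 1.35, 0.688) and reference genes (4 of 8 up, 0.38, 0.249). Carbonic anhydrases (2 up, 2 down, median −0.41, mean 0.38), guard cell markers (2 of 8 up, 0.17, 0.682) and phloem markers (2 of 3 up, 0.70) did not pass either. Clock genes (9 up, 1 down of 17, 0.63, adjusted p = 0.0664) and ER stress genes (6 of 7 down, −2.23, or −1.06 without wild-type LC replicate 1; 0.0664) passed with a replicate block only (adjusted p = 0.0282 and 0.0358).

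In glyk1 in LC, 11326 genes differed from the wild type, 5480 up and 5846 down (4850 and 5569 with all rows as deposited, 5791 and 5650 with DESeq2 size factors, 6198 and 5375 without both wild-type replicate 3 libraries). XTH18 (AT4G30280), a xyloglucan-modifying enzyme, rose from 0.0664 ± 0.065 (n = 3) to 902 ± 175 CPM (n = 2; log2 fold change 13.45, SE 1.26, adjusted p = 7.93e-07). AOX1A rose from 40.0 ± 8.09 to 1884 ± 367 CPM (5.70, SE 0.49, adjusted p = 5.34e-07) and SLAH3 (AT5G24030), an anion channel, by 4.43 (SE 0.32, adjusted p = 6.62e-08). RHD2 (AT5G51060), an NADPH oxidase (12.26), UGT74E2 (11.58, SE 1.14), XTR6 (AT4G25810, 10.58, SE 0.85) and HSFA2 (AT2G26150), a heat shock factor (6.85, SE 0.58), rose as well (adjusted p from 1.96e-07 to 1.11e-06 for the last 3). DIN11 was 8130-fold higher (2250 to 67200), ERF71 (AT2G47520) 5370-fold (964 to 212000), and UMAMIT36 (AT1G70260) at least 409-fold lower. XTH31 fell by 9.73, LDOX by 9.76 (SE 2.21, adjusted p = 0.00169), AT5MAT (AT3G29590), an anthocyanin malonyltransferase, by 8.75 and UGT79B1 (AT5G54060) by 8.19. CHLG fell by 2.72 (SE 0.45, adjusted p = 0.000161) and GLK1 by 1.87 (SE 0.22, adjusted p = 4.69e-06). PSAD2 (AT1G03130), a photosystem I subunit, fell by 2.73 (SE 0.56, adjusted p = 0.000796) and RBCS1B (AT5G38430), a small subunit of Rubisco, by 2.63 (SE 0.62, adjusted p = 0.00219). LHCB6 (AT1G15820) fell by 2.44 (SE 0.67, adjusted p = 0.00606, adjusted p = 0.055 without glyk1 LC replicate 1).

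All 12 mitochondrial dysfunction genes (median 5.54, list test adjusted p = 1.86e-06), 11 of 13 oxidative stress genes (2 lower, 4.16, 0.00206), and 5 of 7 heat shock genes (4.66, 0.0234) were higher in glyk1 LC. So were 9 of 17 jasmonate genes (1 lower, 2.40, 0.0234), 9 of 22 salicylic acid genes (1 lower, 1.75, 0.0364), 10 of 21 carbon starvation genes (1.26, 0.0234), 9 of 17 clock genes (2 lower, 0.84, 0.0364) and 5 of 9 senescence genes (2.23, 0.0477). ZAT10 (5.43, SE 0.52), ZAT12 (AT5G59820, 7.14), UPOX (5.16), WRKY6 (4.15, SE 0.36), LOX3 (AT1G17420, 4.34, SE 0.41), PAD4 (AT3G52430, 3.66), DIN10 (5.46, SE 0.70), GDH2 (5.16, SE 0.37), PGDH1 (4.01) and UBQ10 (3.03, SE 0.31) were among the genes that rose. Lower were 13 of 16 chlorophyll synthesis genes (−2.22, 0.000992), and 13 of 16 anthocyanin genes (−3.46, 0.00666). Without wild-type LC replicate 1 the anthocyanin median was −1.34 and that of salicylic acid 3.3. So were 12 of 27 starch and sucrose genes (3 higher, −0.90, 0.0364), 7 of 18 light harvesting genes (−1.20, 0.0364) and 6 of 22 photosystem genes (1 higher, −0.74, 0.0477). With an estimated correlation none of these calls held (adjusted p = 0.239 to 0.699), and with a replicate block light harvesting (adjusted p = 0.102), photosystem (0.207) and senescence (0.0826) did not. Photorespiration (4 up, 12 down of 32, −0.40, 0.196), Calvin-Benson cycle (2 up, 9 down, −0.53, 0.0944), stomatal movement (7 up, 4 down, 0.17, 0.451) and nitrogen assimilation (7 up, 3 down, 0.48, 0.224) did not pass. Neither did ABA response (8 up, 7 down, 0.11, 0.997, mean −0.39), epidermis markers (3 of 6 down, −0.78, 0.0756), guard cell markers (2 of 8 up, 1.02, 0.192) and reference genes (4 of 8 up, 0.37, 0.124). When only these 2 groups were fitted, 7168 genes were called.

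In pglp1 in LC, 12167 genes differed from the wild type, 5529 up and 6638 down (5004 and 6335 with all rows as deposited). UGT74E2 rose to 5583 ± 149 CPM (n = 2) from 0.317 ± 0.173 CPM (n = 3; log2 fold change 14.12, SE 1.22, adjusted p = 1.94e-07). AOX1A rose to 4138 ± 208 CPM (6.79, SE 0.52, adjusted p = 1.02e-07) and UPOX by 7.80 (SE 0.57, adjusted p = 3.81e-08). CAT2 (AT4G35090), the leaf catalase that breaks down photorespiratory peroxide, rose from 215 ± 103 to 3628 ± 440 CPM (4.07, SE 0.39, adjusted p = 4.69e-07). SLAH3 rose from 4.24 ± 1.55 to 221 ± 12.2 CPM (5.70, SE 0.34, adjusted p = 6.19e-09). XTH18 rose by 14.04 (SE 1.27), DTX1 by 13.45 (SE 1.54), ZAT10 by 6.45 (SE 0.54) and HSFA2 by 6.84 (SE 0.58), with adjusted p from 1.47e-07 to 3.1e-06. The gene sks8 (AT1G21850) was at least 2320-fold higher, TPS2 (AT1G16980), a trehalose phosphate synthase family gene, at least 1710-fold and IDL1 (AT3G25655) at least 776-fold. XTH31 was at least 200-fold lower and AT5MAT 314-fold lower (86.8 to 2600). The AT5MAT call was lost without wild-type LC replicate 1 (adjusted p = 0.0992) or pglp1 LC replicate 2 (adjusted p = 0.0539), that of IDL1 with all rows as deposited (adjusted p = 0.0691). PORB (AT4G27440), a protochlorophyllide reductase, fell by 5.13 (SE 0.81, adjusted p = 5.7e-05) and PSAD2 by 3.83 (SE 0.60, adjusted p = 5.31e-05). LHCB2.2 (AT2G05070) fell by 3.24 (SE 0.69, adjusted p = 0.000848), HPR2 (AT1G79870) by 3.09 (SE 0.31, adjusted p = 7.86e-07) and MLP423 (AT1G24020) by 6.99 (SE 1.39, adjusted p = 0.000508). HEMA1 (AT1G58290), the first committed enzyme of tetrapyrrole synthesis, rose by 3.32 (SE 0.52, adjusted p = 5.49e-05). ACT2 (AT3G18780, 2.70, SE 0.23, adjusted p = 2.49e-07) and UBQ10 (2.33, SE 0.30, adjusted p = 9.17e-06), often used as references, were higher.

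Of the lists in pglp1 LC, mitochondrial dysfunction (11 of 12 higher, median 7.29, adjusted p = 5.18e-06), oxidative stress (10 of 13 higher, 1 lower, 2.67, 0.00549) and jasmonate (11 of 17 higher, 3.11, 0.0123) passed at the preset correlation. None passed with an estimated correlation (adjusted p = 0.426, 0.426 and 0.872). The oxidative stress median was 4.49 without wild-type LC replicate 1. LOX4 (AT1G72520) rose by 6.32, JAZ8 by 6.63 and NDA1 (AT1G07180), an alternative NADH dehydrogenase, by 4.63. The other lists did not pass: photorespiration (9 up, 7 down of 32, 0.19, 0.491), Calvin-Benson cycle (8 up, 2 down, 0.49, 0.355), light harvesting (3 of 18 down, 0.15, mean −0.35, 0.934), photosystem subunits (2 up, 8 down of 22, −0.81, 0.355) and chlorophyll synthesis (2 up, 6 down, −0.67, 0.478). Among metabolic and hormone lists, the same held for starch and sucrose (5 up, 15 down of 27, −1.06, 0.177), carbon starvation (7 up, 4 down, 0.63, 0.566), nitrogen assimilation (4 up, 5 down, 0.08, mean −0.08), stomatal movement (8 up, 5 down, 0.02, 0.491) and ABA response (7 up, 9 down, −0.66, 0.989). So it did for anthocyanins (1 up, 7 down, −2.46, or −0.12 without wild-type LC replicate 1; 0.355), salicylic acid (3 up, 4 down, −0.07, 0.08 with DESeq2 size factors and 1.28 without wild-type LC replicate 1), heat shock (5 of 7 up, 3.42, 0.157) and epidermis markers (3 of 6 down, −0.78, 0.464). The medians of photorespiration, light harvesting and stomatal movement turned negative without wild-type LC replicate 1 (−0.01, −0.35 and −0.02). With DESeq2 size factors the log2 fold changes of this comparison moved by 0.14 as a whole.

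The clock genes of pglp1 LC split by their time of day. Morning genes were higher: CCA1 (AT2G46830) stood at 418 ± 37.8 against 5.56 ± 2.14 CPM (6.24, SE 0.37, adjusted p = 6.04e-09). LHY (AT1G01060) rose by 6.55 (SE 0.42, adjusted p = 1.15e-08), RVE8 (AT3G09600) by 7.05 (SE 0.46, adjusted p = 2.76e-08), PRR9 (AT2G46790) by 6.55, RVE1 (AT5G17300) by 6.54, LNK2 (AT3G54500) by 5.09 and LNK1 (AT5G64170) by 2.15. Evening genes were lower, with log2 fold changes of −3.10 for ELF3 (AT2G25930), −3.04 for CCR2 (AT2G21660), −2.69 for ELF4 (AT2G40080), −2.65 for FKF1 (AT1G68050), −1.89 for BOA (AT5G59570) and −0.84 for GI (AT1G22770). PRR5 (AT5G24470) rose by 1.1, whereas PRR7 (AT5G02810, −0.24, adjusted p = 0.348), TOC1 (AT5G61380, −0.63, 0.072) and LUX (AT3G46640, −0.56, 0.0777) did not change. The list test, which asks for a common direction, gave an adjusted p of 0.419 (median −0.24, mean 1.51). CCA1 was also higher in shm1 LC (2.26) and glyk1 LC (2.69), as was LHY (2.90 and 2.40).

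**Figure D3:**
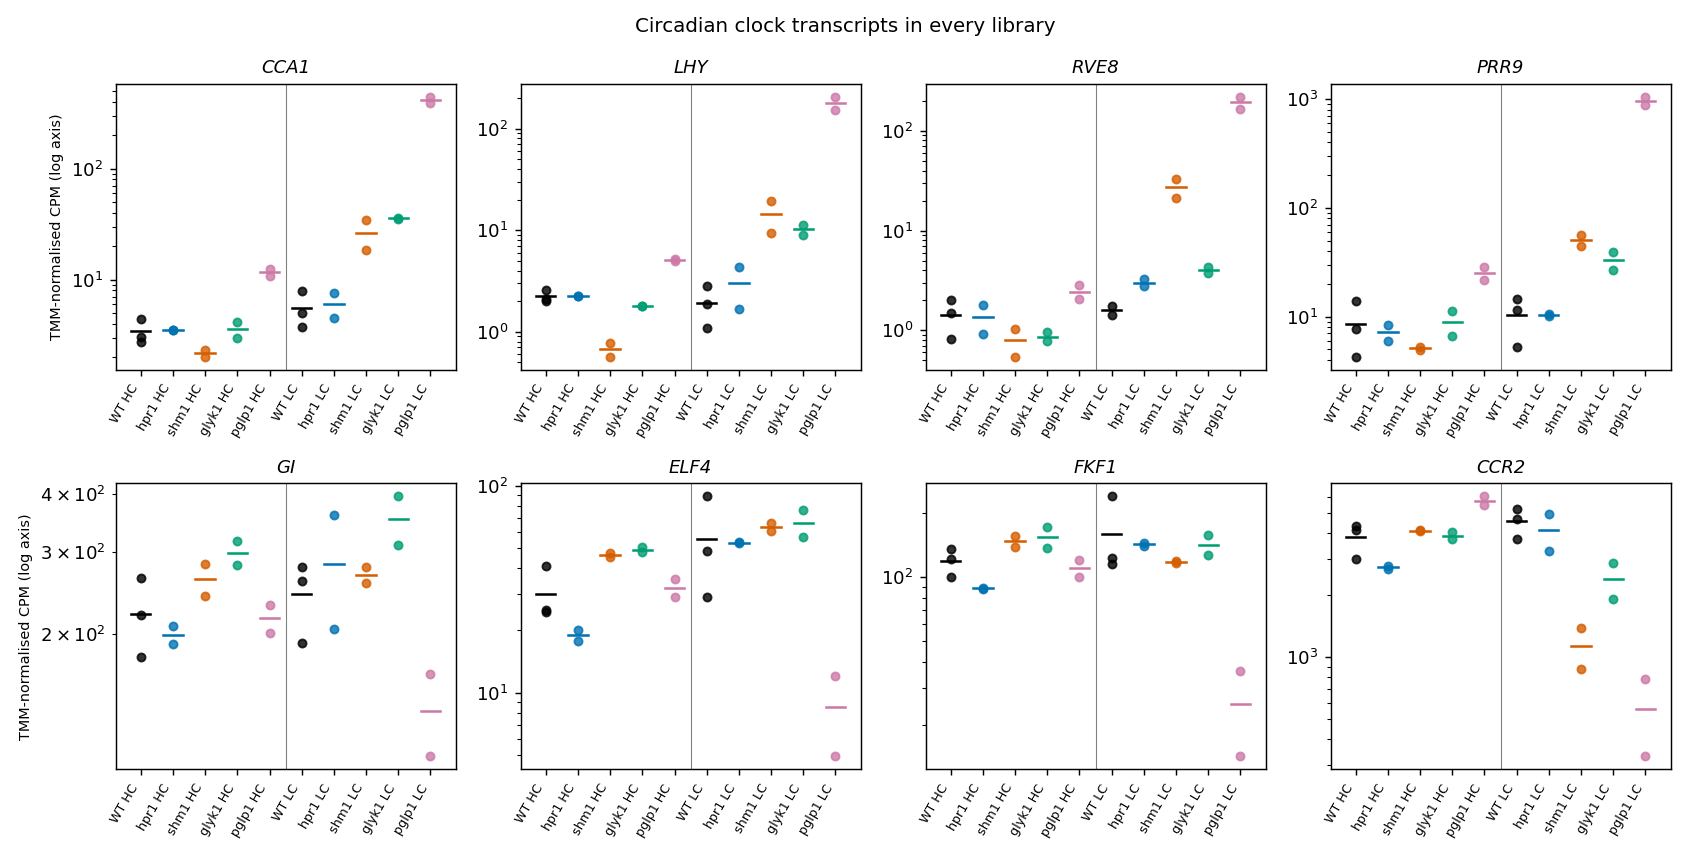
Clock transcripts per library (TMM-normalised CPM, log axis; points are libraries, lines group means). CCA1 rose by 6.24 and ELF4 fell by 2.69 log2 units in pglp1 LC against the wild type.

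**Figure D4:**
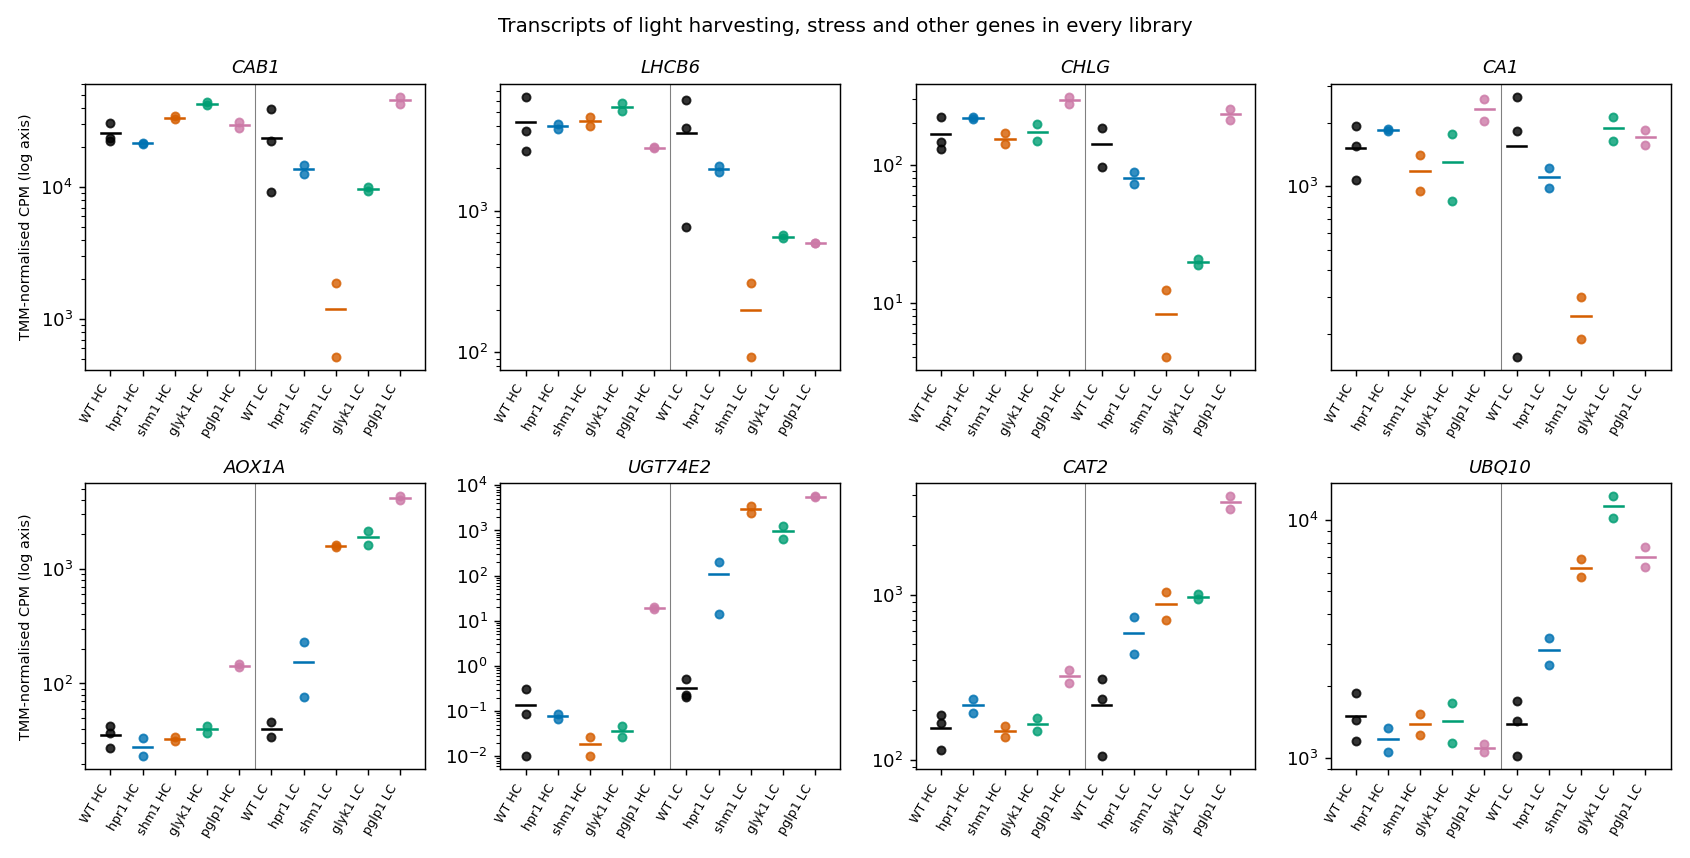
Transcripts of photosynthesis and of stress per library (TMM-normalised CPM, log axis; values under 0.01 in UGT74E2 are drawn at 0.01). CAB1 fell by 4.29 log2 units in shm1 LC and CAT2 rose by 4.07 in pglp1 LC against the wild type.

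In all 4 mutants in LC, 467 genes differed from the wild type in the same direction, 367 up and 100 down (237 and 60 with all rows as deposited, 214 and 51 with a replicate block). With independent comparisons 10.5 and 4.5 would be met. In 10 simulations of unchanged groups, all 22 libraries were drawn as independent counts around the wild-type HC means. The 4 comparisons shared the simulated wild type. Each simulation made at most 1 call, so 0 genes were called in all 4. At an unadjusted p under 0.05 in all 4 their median was 26 genes, against 1497 up and 701 down in the data. The drawn wild type lacks the differences between the real wild-type LC libraries, so it cannot show what sharing those libraries adds. Independent comparisons leave out the shared libraries, and the simulations leave out the effects and those differences. The excess over either is thus not all separate evidence. CYP81D11 rose by 10.09, 11.96, 5.65 and 9.93 (hpr1, shm1, glyk1, pglp1; adjusted p = 0.292 in glyk1 with all rows as deposited), DOGT1 (AT2G36800), a glucosyltransferase, by 4.78, 7.99, 6.09 and 9.32, and MO1 (AT4G15760), a monooxygenase, by 3.52, 6.54, 6.21 and 8.44. OPR1 (AT1G76680, 4.15, 7.28, 5.09 and 5.18) and OPR2 (AT1G76690, 2.99, 5.96, 1.96 and 5.01), oxophytodienoate reductases, and DHAR2 (AT1G75270), a dehydroascorbate reductase (2.39, 4.66, 3.16 and 3.02), rose as well. GT18 (AT5G62220), a glycosyltransferase (−1.80, −1.84, −2.25 and −3.82), and IQD30 (AT1G18840), a calmodulin-binding protein (−1.30, −3.08, −2.55 and −2.30), fell. So did AKR4C10 (AT2G37790, −1.56, −4.01, −2.38 and −1.70) and DREB1A (AT4G25480), a cold response factor (−1.63, −2.75, −2.89 and −2.74), whose calls in hpr1 were lost without hpr1 LC replicate 1 (adjusted p = 0.0688 and 0.0507). The 3 mutants other than hpr1 shared 3022 genes up and 2950 down, against 494 and 629 with independent comparisons and 0 in the simulations, with the same limits. The count for all 4 followed the hpr1 comparison: it was 110 without hpr1 LC replicate 1, 279 without wild-type LC replicate 2, 994 without wild-type LC replicate 1, and 0 when each pair of groups was fitted alone (1034 with DESeq2 on all libraries).

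In HC, few genes other than the targeted ones separated hpr1, shm1 or glyk1 from the wild type. In hpr1 the only call was HPR1 (584 genes at an unadjusted p under 0.05; DESeq2 called 7), and in glyk1 the only call was GLYK (2208; DESeq2 called 329). No gene was called in all 4 mutants (4 up and 35 down at an unadjusted p under 0.05 in each, against a median of 19 in simulations of unchanged groups; 1 called by DESeq2). In shm1, 4 genes were called, 1 up and 3 down (1 and 2 with all rows as deposited; DESeq2 called 156). Without either shm1 HC library 0 were called (963 and 777 at an unadjusted p under 0.05). NAP12, an ABC transporter family gene, had 0 counts in the wild type and 33.4 ± 9.93 CPM in shm1 HC (at least 1990-fold, adjusted p = 0.00587). This call was lost without shm1 HC replicate 1 (adjusted p = 0.0832) or replicate 2 (adjusted p = 0.104) and with a replicate block (adjusted p = 0.0662). In shm1 LC it stood at 38.5 and 39.3 CPM, and outside shm1 it did not exceed 0.0263 CPM in any library.

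In pglp1 in HC, 821 genes differed, 330 up and 491 down (176 and 195 with all rows as deposited, 269 and 264 with a replicate block). TPS2 had 0 counts in the wild type and 103 and 45.6 CPM in pglp1 HC (at least 4020-fold), and 47.5 and 108 CPM in pglp1 LC. UGT74E2 rose from 0.131 ± 0.158 (n = 3) to 19.2 ± 1.4 CPM (n = 2; log2 fold change 7.75, SE 1.06, adjusted p = 0.00167). NIA1 (AT1G77760), nitrate reductase, rose from 16.1 ± 3.05 to 362 ± 196 CPM (4.49, SE 0.55, adjusted p = 0.000692) and ASN2 (AT5G65010), an asparagine synthetase, by 2.83 (SE 0.33, adjusted p = 0.000654). CCA1 rose by 1.77 (SE 0.32, adjusted p = 0.01, adjusted p = 0.0871 without pglp1 HC replicate 2). WRKY38 (AT5G22570), a defence factor, fell by 4.31 (SE 1.09, adjusted p = 0.0403, adjusted p = 0.226 and 0.378 without pglp1 HC replicate 1 or 2, 0.071 and 0.0785 without wild-type HC replicate 1 or 2, 0.0506 with a replicate block, 0.0605 without a filter and 0.0654 with all rows as deposited). Higher as lists were mitochondrial dysfunction (4 of 12, median 0.74, adjusted p = 0.000344), starch and sucrose (0 of 27, 0.41, 0.00287) and circadian clock (3 of 17, 0.50, 0.000123). Nitrogen assimilation was higher by its mean (4 of 14, median −0.07, mean 0.74, adjusted p = 0.0374, a median of 0.04 with DESeq2 size factors). Salicylic acid (1 of 22, −2.28, 7.62e-06) and jasmonate (1 of 17, −1.66, or −1.53 with low-count genes at their bound; 0.000777) were lower. All 6 calls were lost with an estimated correlation (adjusted p = 0.254 to 0.602). The count was 163 (132 up, 31 down) without pglp1 HC replicate 1, 48 (40 and 8) without replicate 2, and 274 (110 and 164) without wild-type HC replicate 2, and DESeq2 called 2024. Genes up outnumbered genes down with DESeq2 size factors (486 and 366).

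In the other mutants, list shifts in HC had no changed members apart from the targeted genes. Jasmonate genes were lower in hpr1 (median −0.97, adjusted p = 2.64e-07), shm1 (−1.16, 5.02e-05) and glyk1 (−1.76, 8.28e-12; 9 of 17 adjusted over the list alone). Anthocyanin genes were lower too (−0.87, −1.93 and −1.91; −0.83 and −1.61 with low-count genes at their bound in hpr1 and shm1; 0.00455, 5.02e-05 and 1.94e-05). ABA response genes were lower in hpr1 (−0.89, 8.29e-10) and higher in shm1 (0.48, 0.00637) and glyk1 (0.55, 0.00194), and carbon starvation genes were higher in shm1 (0.55, 5.3e-05) and glyk1 (0.80, 0.000599). Light harvesting (0.64, 0.00987) and photosystem genes (0.42, 0.00987) were higher and salicylic acid genes lower (−0.67, 0.00987) in glyk1; photorespiration (−0.22, 0.0256) was lower in shm1. Calvin-Benson genes were lower in shm1 (−0.31, 0.00373) and glyk1 (−0.20, 0.0377), but not with a replicate block (adjusted p = 0.204 and 0.515). With an estimated correlation all these calls were lost (adjusted p = 0.28 to 0.959). With a replicate block, photosystem genes passed as higher in hpr1 (from 0.7 to 0.00393) and shm1 (from 0.0851 to 0.000132). So did light harvesting in both (0.0396 and 0.000831), Calvin-Benson (0.0129) and chlorophyll genes (0.00742) in hpr1, and Calvin-Benson (0.00115) and photorespiration genes (0.012) in pglp1. ER stress genes passed as lower in shm1, glyk1 and pglp1 (0.00584, 0.038 and 0.0109) and epidermis markers as higher in shm1 and glyk1 (0.0325 and 0.0493). Phloem markers were higher in glyk1 (0.038), senescence genes lower in pglp1 (0.047), and oxidative stress (0.0393) and starch genes (0.0367) lower in shm1, again with the block only.

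From HC to LC, 3085 genes changed within hpr1 (1791 up, 1294 down), 13301 in shm1 (6777 and 6524), 11212 in glyk1 (5171 and 6041) and 11209 in pglp1 (5387 and 5822). All rows as deposited gave 1031 and 698, 5929 and 5918, 4393 and 5349, and 4738 and 5162. The larger direction turned with DESeq2 size factors in glyk1 (5933 and 5189) and pglp1 (5846 and 5481), and in glyk1 also without both wild-type replicate 3 libraries (6659 and 5377). In hpr1, CYP81D11 was 4760-fold higher in LC (1320 to 39300) and PDF2 (AT4G04890), an epidermal homeobox gene, fell by 1.52 (SE 0.19, adjusted p = 0.000938). UGT74E2 rose by 10.42 (SE 1.38, adjusted p = 0.00118) and XTH31 fell by 5.46 (SE 0.90, adjusted p = 0.00481), calls lost without hpr1 HC replicate 1 (adjusted p = 0.0579 and 0.0583), the latter also with all rows as deposited (adjusted p = 0.0581). In shm1, UGT74E2 was 181000-fold higher (32600 to 7170000), CYP89A6 (AT1G64940) at least 6590-fold and UGT73C1 at least 5640-fold, WRKY6 rose by 7.05 (SE 0.48, adjusted p = 9.26e-08) and GASA6 (AT1G74670), a gibberellin-regulated gene, fell by 8.50 (SE 1.49, adjusted p = 0.000151). In glyk1, UGT74E2 rose by 14.57 (SE 1.52, adjusted p = 2.87e-06), AOX1D (AT1G32350) was 18800-fold higher (6440 to 91300) and XTH31 fell by 8.65. In pglp1, ELI3-2 (AT4G37990) was at least 1790-fold and RAP2.6 (AT1G43160) at least 1630-fold higher, GER3 (AT5G20630), a germin-like gene, 2110-fold lower (720 to 10200; adjusted p = 0.0876 and 0.0908 without pglp1 LC replicate 1 or 2), RFC3 (AT3G17170) fell by 6.61 (SE 0.94, adjusted p = 4.31e-05), and CAT2 (3.50) and RVE8 (6.33) rose.

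Mitochondrial dysfunction genes rose from HC to LC in every mutant (8 of 12 in hpr1, all 12 in the others; medians 2.59, 5.90, 6.12 and 6.35; list test adjusted p = 5.55e-06, 1.56e-05, 1.28e-06 and 8.04e-06). So did jasmonate (11, 12, 15 and 14 of 17, 2.47, 3.01, 4.97 and 4.97) and oxidative stress genes (7, 10, 8 and 8 of 13, 2.39, 5.18, 5.68 and 5.16). Carbon starvation (15 of 21, 2.11, adjusted p = 2.61e-07), ABA response (10 of 22, 1.35, 3.76e-05), senescence (5 of 9, 2.00, 0.000155), clock (4 of 17, 0.67, 0.000764), anthocyanin (2 of 16, 2.29, 0.00934) and salicylic acid genes (2 of 22, 2.04, 0.00449) were higher in hpr1. Chlorophyll synthesis (2 of 16, −0.97, 0.00305), photosystem (0 of 22, −0.57, 0.00376), Calvin-Benson (1 of 24, 1 higher, −0.39, 0.0442) and epidermis genes (3 of 6, −1.11, 0.00425) were lower there. Light harvesting genes of hpr1 (median −0.58, list test adjusted p = 0.0516) passed as lower with a replicate block only (adjusted p = 0.0464). Higher in shm1 were senescence (8 of 9, 4.60, 0.00437), nitrogen assimilation (8 of 14, 2 lower, 1.64, 0.0258) and clock genes (8 of 17, 1 lower, 0.56, 0.0336). In glyk1 they were senescence (5 of 9, 2.07, 0.0173), salicylic acid (13 of 22, 1 lower, 3.24, 0.00243) and clock genes (9 of 17, 1 lower, 0.91, 0.0165), and in pglp1 ABA response (11 of 22, 1 lower, 1.73, 0.0362) and salicylic acid genes (11 of 22, 1 lower, 2.04, 0.0253). In shm1, light harvesting (17 of 18, −4.17, 1.56e-05), photosystem (all 22, −3.36, 1.43e-07) and chlorophyll synthesis genes (15 of 16, −3.50, 1.56e-05) were lower, as were Calvin-Benson (20 of 24, −2.37, 7.78e-05), photorespiration (20 of 32, −1.37, 0.00808), starch and sucrose (20 of 27, −2.13, 0.00077) and epidermis genes (5 of 6, −2.77, 0.00467). In glyk1, light harvesting (15 of 18, −2.18, 0.00226), photosystem (14 of 22, −1.29, 0.00226), chlorophyll synthesis (14 of 16, −2.52, 0.000117) and epidermis genes (4 of 6, −1.59, 0.0211) were lower. In pglp1, starch and sucrose genes were lower (16 of 27, −1.21, 0.0253). Heat shock genes rose in shm1 (6 of 7, 6.86, or 4.76 with low-count genes at their bound; 0.0218), glyk1 (5, 6.31, 0.00468) and pglp1 (5, 4.65, or 4.11 at their bound; 0.0335). With an estimated correlation these calls were lost (adjusted p = 0.2 to 0.811). The hpr1 count was 32 without HC replicate 1, 813 without HC replicate 2, 1821 without LC replicate 1 and 535 without LC replicate 2, and DESeq2 called 4744.

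The response to LC differed from that of the wild type for 24 genes in hpr1 (21 up, 3 down), 10922 in shm1 (5566 and 5356), 7976 in glyk1 (3853 and 4123) and 8404 in pglp1 (4218 and 4186). All rows as deposited gave 6 and 1, 4809 and 4828, 3199 and 3703, and 3641 and 3675. The larger direction turned in glyk1 with DESeq2 size factors (4309 and 3689) and without both wild-type replicate 3 libraries (4875 and 3460), and in shm1 with size factors (5545 and 5575). The counts that follow are sums over the libraries of a group, in HC and then in LC. They are not scaled, and groups differ in depth and in number of libraries. A rise or fall between groups can therefore not be read from them, and the log2 differences come from the scaled fit. DOGT1 had 91 counts in hpr1 HC and 10421 in hpr1 LC against 402 and 300 in the wild type (log2 difference 5.33, adjusted p = 0.0594 without hpr1 HC replicate 1). MIPS1 had 12444 and 3262 against 36496 and 10180 (−2.43, adjusted p = 0.076 without hpr1 HC replicate 1 and 0.0518 without hpr1 LC replicate 1). In shm1, GASA6 had 10693 and 127 counts against 6203 and 3138 in the wild type (−9.05), and CER1 (AT1G02205), a wax synthesis gene, had 6520 and 135 against 2284 and 1605 (−8.81). In glyk1, EXPA8 (AT2G40610), an expansin, had 25961 and 73 against 9922 and 2248 (−7.45), and in pglp1 NUDT24 (AT5G19470) had 141 and 4 against 467 and 1563 (−7.92). At the preset correlation 7, 6, 5 and 5 lists passed as higher in these responses and 3, 7, 4 and 1 as lower. Mitochondrial dysfunction (medians 2.31, 5.84, 6.09 and 5.89) and jasmonate genes (2.19, 2.62, 4.14 and 4.56) responded more in every mutant than in the wild type at the preset correlation (list test adjusted p = 1.62e-07 to 0.0151; adjusted p = 0.187 to 0.671 with an estimated correlation). With a replicate block the response calls of salicylic acid in hpr1 (from 0.017 to 0.0505), epidermis in glyk1 (0.0492 to 0.0708) and heat shock in shm1 and pglp1 (0.0363 to 0.0628 and 0.0434 to 0.074) were lost. In hpr1 the count was 351 with DESeq2 and 0 with edgeR on its own groups alone (1447 at an unadjusted p under 0.05). It was 207 without wild-type LC replicate 1, 101 without hpr1 LC replicate 2, and 1 to 15 without hpr1 HC replicate 1 or 2, hpr1 LC replicate 1, wild-type HC replicate 1 or 2 or wild-type LC replicate 2.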

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

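The comparisons of responses were fixed before the data were examined; every test in the paragraphs on displaced rows, wild-type LC replicate 2 and the clock was chosen after the result it addresses had been seen.

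Genes are listed here because their response to LC differed between a mutant and the wild type: 24 in hpr1, 10922 in shm1, 7976 in glyk1 and 8404 in pglp1. Counts given below are sums over the libraries of a group and are not scaled to depth, so changes between groups cannot be read from them. The 3 largest rises and falls per mutant with a symbol follow as log2 differences of responses. In hpr1 they were CYP81D11 (12.15, 2 counts in hpr1 HC, 15214 in hpr1 LC, 24 in wild-type HC, 6 in wild-type LC), DOGT1 (5.33) and CML38 (4.52), and MIPS1 (−2.43), GT18 (−2.03) and SGB1 (−2.0). In shm1 they were UGT73B4 (19.12, counts 0, 38557, 29 and 1 in the same order of groups), LCR67 (18.47, counts 0, 12200, 8 and 0) and DIN11 (17.75, counts 43, 338579, 793 and 2). Falls were largest for GASA6 (−9.05), CER1 (−8.81) and RD29B (−8.14, counts 310, 79, 729 and 4334). In glyk1 they were GSTU3 (16.86, counts 1, 16417, 218 and 8), SUC7 (16.75, counts 0, 3218, 41 and 1) and CYP710A1 (15.43, counts 1, 6472, 419 and 16). There the largest falls were LDOX (−9.0, counts 31, 13, 62 and 9382), XTH31 (−8.62, counts 2996, 4, 4623 and 1351) and EXPA8 (−7.45). In pglp1 they were GSTU3 (17.73, counts 0, 1602, 218 and 8), BHLH92 (15.74, counts 0, 1148, 17 and 2) and SUC7 (15.12, counts 1, 2482, 41 and 1). Lower were XTH31 (−13.48, counts 750, 0, 4623 and 1351), GER3 (−10.22, counts 9102, 3, 25297 and 6119) and NUDT24 (−7.92). Without wild-type HC replicate 1, UGT73B4 and LCR67 in shm1, GSTU3 and SUC7 in glyk1 and GSTU3, SUC7 and BHLH92 in pglp1 lost their call (adjusted p = 0.0804 to 1.0). LDOX in glyk1 lost it without glyk1 HC replicate 2 or LC replicate 1 (adjusted p = 0.0514 and 0.0781). GER3 lost it on leaving out most libraries (adjusted p = 0.0523 to 0.136), as did CML38, GT18 and SGB1 (adjusted p = 0.0502 to 0.484), and CYP81D11 with all rows as deposited (adjusted p = 0.225). Where a group has 0 to 3 counts, the fitted value depends on the prior count and is no bound. LDOX stood at 298 CPM in wild-type LC replicate 1 and at 9.92 and 3.61 CPM in the other wild-type LC libraries.

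Wild-type LC replicate 3 does not follow the other libraries along a stretch of chromosome 3, with a median window correlation of −0.078 as deposited. Counts written on displaced rows would bring it back up at another row shift, and at the best shift of each window (median 5 rows) it was 0.968. The windows were picked by their gain at the best shift, so that value was largely set by the choice. At 1 common shift of the whole stretch, r was 0.002 at 0 rows, 0.478 at 4 and 0.507 at 5, and at most 0.105 at the other shifts up to 6 rows, so this explanation fits. A low depth of the library would lower the correlation everywhere, but outside the displaced rows it was 0.979, so depth goes against it. Of 1723 loci inside the blocks 860 lay at least 8-fold below every other wild-type library, against 69 of 7830 outside.

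Few genes (4) were called between wild-type LC and HC and the wild-type LC libraries were unlike each other, but displaced rows go against the data as the cause: calls numbered 4 as deposited and 4 with those rows dropped, a step that took the hpr1 response from 7 to 20, and outside these rows the wild-type LC libraries had rank correlations of 0.892 to 0.935 (wild-type HC 0.948 to 0.976). Separate processing of both replicate 3 libraries stays open, since leaving them out (4 calls) also takes 2 libraries from the test (1430 genes at an unadjusted p under 0.05, from 1907). That LC replicate 2 was an HC library or was not shifted was tested after rank correlations had shown it close to wild-type HC: on a score from the genes changed in hpr1 from HC to LC (1427 up, 1023 down) it had 0.21, against 0.66, −0.15 and −0.51 in wild-type HC and 1.37 and 0.87 in the other wild-type LC libraries. This score parts wild-type libraries weakly, since LC replicate 3 lay above the highest HC score by less than the SD of the HC scores (0.60). At AT1G29660, the gene with the widest gap between HC and LC libraries, LC replicate 2 lay −0.15 log2 units from the nearest HC library. In a test chosen once that result was known, LC replicate 2 lay over 1 log2 unit beyond the HC libraries for 1 gene (3 to 9 for wild-type HC libraries left out in turn, 83 and 19 for the other wild-type LC libraries). These fit, yet AT5G15120 (0.694 CPM, 10 counts, HC 7.59 to 17.8, other LC 0.195 to 2.47), LBD41 (2.36 CPM, HC 5.66 to 33.2, other LC 1.3 to 25.1) and AT3G06435 (0.694 CPM, HC 4.45 or more, other LC 0.325 to 5.99) lay below every HC library there. All 3 were called with this library in the LC group, and the 4 wild-type calls held without it too. The ranges of the last 2 overlap across genotypes but not within the wild type. There LBD41 stood at 23.4 to 25.9 CPM in HC against 1.3 and 2.81 in LC replicates 1 and 3. AT3G06435 stood at 4.88 to 8.26 against 0.325 and 0.86, AT5G15120 at 12.5 to 14.1 against 0.195 and 0.344 CPM. These 3 genes place LC replicate 2 with wild-type LC, the score and AT1G29660 with HC. An HC library was thus neither shown nor excluded, a weaker or shorter exposure was not tested, and the labels were kept.

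Of 10 splits of the 6 wild-type libraries, 3 gave at least 4 calls, the real one (4) and 2 others (1272 and 21), and 10 splits are too few for a share under 0.05. The highest other, 1272, sets HC replicates 1 and 2 and LC replicate 1 against the rest. Those are also the deepest wild-type libraries (82.0, 66.5 and 24.6 M counts against 18.1, 11.98 and 17.2 M). Depth and other differences between libraries cannot be told apart there. Both replicate 3 libraries fall together there, but also in 3 splits with 0 calls (1820, 1573 and 3110 genes at an unadjusted p under 0.05), so this alone does not account for the 1272. With a replicate block the real split gave 4 in the fit of all 22 libraries and 0 in the 6 wild-type libraries alone (1084 genes at an unadjusted p under 0.05).

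Morning clock transcripts were high and evening ones low in pglp1 LC, listed for opposite directions within a list. Scaling would move all genes one way, while 6 of 14 changed clock genes moved in the minor direction with TMM and DESeq2 size factors. A harvest at another hour than labelled predicts directions from known phases, and 13 of 14 moved as in a morning harvest, PRR5 (1.1) against. The pattern was picked by these directions, so neither count is a separate test. Harvest time cannot be told from a genotype effect on the clock. Both pglp1 LC libraries show the pattern and no pglp1 library was sampled at another hour. An earlier form of the harvest test was replaced after its result was seen.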

How the results depend on the processing

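The alternatives named as added in the methods were chosen after the data were seen; all others were fixed before the data were examined. No called gene among those named changed direction under any alternative, but some list medians did, such as that of anthocyanins in hpr1 LC (−2.29, and 0.12 without wild-type LC replicate 1), and so did the larger direction of some comparisons, such as pglp1 in HC (330 up and 491 down, 486 and 366 with DESeq2 size factors). Unless a value or the smaller number of libraries shows it, the cause was not tested. The replicate block changed the counts of shm1 against the wild type in HC (from 4 to 1), pglp1 in HC (821 to 533), hpr1 in LC (578 to 316) and all 4 mutants in LC (467 to 265). A block in the 6 wild-type libraries alone gave 0 for wild type LC against HC. Of the other main counts none moved more than 1.5 times, and list calls numbered 164 against 152. Crossing the numbers of the hpr1 LC libraries gave 1941 up and 1481 down, uncrossed 1940 and 1485. On simulated data both tools exceeded 5% false calls, edgeR in 1 of 3 comparisons with changed genes (9.4%) and DESeq2 in all 3 (16.2% to 24.3%). DESeq2 called 212 genes for wild type LC against HC, 4744 for hpr1 LC against HC, and 7, 156, 329 and 2024 for hpr1, shm1, glyk1 and pglp1 in HC. It called 1433 for hpr1 in LC, 351 for the hpr1 response minus that of the wild type, and 1034 and 1 for all 4 mutants in LC and HC. With only the groups compared, fewer libraries estimate the spread. The counts were 0 for wild type LC against HC, 0 for shm1 in HC and 356 for pglp1 in HC. They were 0 for hpr1 in LC, 7168 for glyk1 in LC, 0 for the hpr1 response and 0 for all 4 mutants in LC. SHM1 in shm1 HC stood at −4.27 (SE 0.35, adjusted p = 0.0675) and HPR1 in hpr1 LC at −7.1 (SE 0.64, adjusted p = 0.225). All rows as deposited gave 1729 for hpr1 LC against HC, 371 for pglp1 in HC, 359 for hpr1 in LC, 7 for the hpr1 response and 297 for all 4 mutants in LC. DESeq2 size factors gave 7 for shm1 in HC and 15 for the hpr1 response. They moved log2 fold changes as a whole by 0.22 in glyk1 LC against HC, 0.14 in pglp1 LC against the wild type, −0.11 in the hpr1 and 0.14 in the glyk1 response. Without both wild-type replicate 3 libraries 2 genes were called for shm1 and 2 for glyk1 in HC, and log2 fold changes moved by 0.27 in glyk1 LC against HC and 0.18 in the glyk1 response. Neither filter moved a count more than 1.5 times. Of 152 list calls 3 held with an estimated correlation; size factors gave 148. Of 165 calls with fry 92 were shared, and it called no list (0) in wild type LC against HC, hpr1 in LC, the hpr1 response, or hpr1, shm1 and glyk1 in HC. Of 174 list medians of at least 0.3 in size in comparisons with wild-type LC, 61 moved over 1.5 times without wild-type LC replicate 1, 10 of them across 0, and 22 without replicate 2. Of 312 in all comparisons 51 moved without both wild-type replicate 3 libraries and 5 with DESeq2 size factors.

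Leaving out one library at a time gave 3 to 183 genes for wild type LC against HC (4 with all), 32 to 1821 for hpr1 LC against HC (3085), 11127 to 12179 for shm1 (13301), 8369 to 9507 for glyk1 (11212) and 8955 to 9716 for pglp1 (11209). In HC it gave 1 to 3 for hpr1 (1), 0 to 5 for shm1 (4), 1 to 2 for glyk1 (1) and 48 to 635 for pglp1 (821). In LC it gave 176 to 1369 for hpr1 (578), 11091 to 13498 for shm1 (13496), 7720 to 11441 for glyk1 (11326) and 10031 to 12151 for pglp1 (12167). Responses minus that of the wild type ranged over 1 to 207 for hpr1 (24), 8844 to 11426 for shm1 (10922), 5390 to 8872 for glyk1 (7976) and 6793 to 8960 for pglp1 (8404). All 4 mutants ranged over 110 to 994 in LC (467) and 0 to 0 in HC (0; 4 genes up and 35 down at an unadjusted p under 0.05 in all). SHM1 in shm1 HC ranged from −4.46 to −4.11 and PGLP1 in pglp1 HC from −3.08 to −2.85. Of the named genes, calls were lost in 84 of 631 cases with only the groups compared, 40 of 634 with all rows as deposited, 13 of 634 with a replicate block and 210 of 3630 on leaving out a library. Genes whose displaced rows were masked rest on 2 wild-type LC libraries. Depth limits hpr1 LC replicate 1 (5.91 M counts) and pglp1 HC replicate 1 (9.14 M), where genes of low expression rest on few counts. The pseudocount alternative was not run because counts were at hand.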

Other observations

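The low-oxygen list and its test were chosen after LBD41 and AT5G15120 had been seen to fall. From HC to LC AT5G15120 also fell in hpr1, shm1, glyk1 and pglp1 (−4.32, −4.89, −5.24 and −2.17). AT3G06435 fell in the first 3 (−2.09, −2.44 and −2.54), not past the threshold in pglp1 (−0.83, adjusted p = 0.0755). LBD41 fell in hpr1 (−2.44, adjusted p = 0.00149), rose in pglp1 (1.54, 0.000903) and did not pass in shm1 (−0.54, 0.135) or glyk1 (−0.64, 0.0891). Other listed genes went both ways in shm1, glyk1 and pglp1, as ERF71 (10.75, 10.85 and 6.45) and AT3G10040 (−3.74, −3.83 and −4.76).

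A hypothesis is that genes known to rise at low oxygen had lower expression in wild-type LC than in HC. It predicts that the other genes of that kind shift down as a group. Of 11 such genes 7 had a negative log2 fold change (median of the list −0.52), and none of the list passed the threshold (adjusted p = 0.128 to 1). Negative were ETR2 (−2.26), AT5G39890 (−1.97), HB1 (−1.74), SUS4 (−1.64, SE 1.37), AT3G10040 (−1.13), ACO1 (−0.52) and ERF71 (−0.03, SE 3.02). Positive were ADH1 (1.59), AT4G33070 (0.52), SUS1 (0.39) and ERF73 (0.17), so not all fell. For the list, limma's camera gave p = 0.0326 at the preset correlation and p = 0.0474 with an estimated correlation of 0.028. This fits, but only just. Oxygen was not measured in these data, and the test does not say why the list shifted.

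At a q-value under 0.01, the authors' deposited table has 5 loci higher and 0 lower in the wild type in LC against HC, and 447 and 112 in hpr1, 3349 and 2955 in shm1, 3129 and 1935 in glyk1 and 3577 and 2367 in pglp1. Against the wild type in LC, it has 2 higher and 1 lower in hpr1, 420 and 3 in shm1, 364 and 2 in glyk1, and 435 and 5 in pglp1. In HC it has 0 and 5, 20 and 7, 10 and 17, and 116 and 93.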
